A study of Homo sapiens with 11 samples.

How the data were processed

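The series holds 11 Affymetrix HG-U133 Plus 2 arrays of total RNA from T47D cells, per the labels' protocols. The deposited table gives 1 value per probe set and array for 54675 probe sets. The method of summarisation and normalization and the log base were not given in the sources used here. The deposited values were read as log2, from their size and spread. They had already been normalised across arrays by the authors, since every array's median lay within 0.0106 of 0 before any step taken here, and each probe set had been centred on a baseline shared by the arrays. In 56.9% of probe sets 1 positive and 1 negative value lay at equal distance from 0 (tolerance 1e-05), and in 0.772% a value was 0, as a median over more arrays than these 11 would leave them. The direction is taken as deposited, with higher values read as more transcript.

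This centring removed the expression level of each probe set, which had 3 effects. The expression filter fixed for the analysis, and the alternatives of no filter and of only the probe sets highest by mean, could not be applied, nor could an intensity trend in the prior variance, and no pseudocount was needed. Where a gene had several probe sets, the one with the highest mean could not be chosen, and the probe set with the largest SD over the 11 arrays after removing each array set's mean was used. Random lists were matched on the number of probe sets per gene in place of mean expression. No signal over background can be given, so weakly detected probe sets stay in all tests.

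The 62 control probe sets of the array were left out of the tests, leaving 54613. By the platform's annotation, 41091 of these had 1 gene symbol, 1801 had several and 11721 had none, and 41037 symbols were updated through gene identifiers of the RefSeq table. No gene was named from a probe set with several symbols, and the named probe sets covered 19775 genes. No genome was used here, so no coordinates are given.

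Samples were grouped by their labels into 9 groups, 2 with 2 arrays (control and E2-BSA) and 7 with 1. Tests were run with limma 3.58.1 in R 4.3.3. A model of group means over all 11 arrays was fitted to each probe set with lmFit and eBayes, comparisons were contrasts of that fit, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with calls at an adjusted p under 0.05. A group with 1 array was assumed to vary like the 2 replicated groups. E2-BSA over 3 backgrounds was fitted to 8 arrays with E2-BSA and the antagonist as terms. Estradiol against ethanol, 1 array each, was described by the number of probe sets with a log2 difference of 1 or more, with no test. Errors are standard errors of the moderated fit unless named SD, and intervals are 95% confidence intervals. With no change at all, a share of 0.05 of the probe sets tested would be expected at an unadjusted p under 0.05. Every such count given without the array set as a block lies below that share. There the split between the array sets stays in the residual spread, so a low count does not show that no gene responded.

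The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Several choices were made after the data were seen. These are the array set as a block, in every comparison, the comparison of estradiol with control alone, the direct comparison of estradiol with E2-BSA, the comparisons of each combination with its antagonist, the fit to the larger array set alone, robust eBayes, the fit to probe sets with 1 gene, quantile normalization and the compared groups alone with the block, and the 78 probe sets chosen in the smaller set. With the block the model of group means has 1 residual degree of freedom, which comes from the difference between the E2-BSA responses of the 2 array sets, and its errors lean on the prior (11.3 prior degrees of freedom).

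Named genes were taken per comparison from the 12 highest and 12 lowest changes among calls for E2-BSA against control, E2-BSA over 3 backgrounds, ICI, G15 and the added comparison of estradiol with control, and from the 5 highest and 5 lowest for the others. Empty places were filled by the lowest unadjusted p in that direction, given as values that did not pass. Symbols of uncharacterised loci, antisense transcripts, host genes and small RNAs were passed over. For estradiol against ethanol the names come from the 12 highest and 12 lowest differences. Up to 4 members were named for lists that passed, and ESR1, ESR2, GPER1, PGR, TFF1, GREB1, MYC, EGR3, CCND1 and FOS always. One more item fixed for naming is not reported here. Genes named beyond this rule were chosen after their values were seen.

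Gene lists were written from textbook knowledge, with 28 lists in all, and overlap in places. They were tested with camera at a preset correlation of 0.01 between genes, with the correlation estimated from the data as a first alternative and fry as another. At the preset correlation, camera takes its degrees of freedom from the number of genes, so its p does not measure the spread between arrays. With an estimated correlation, camera takes its p from the residual degrees of freedom. The blocked model of group means has 1, so almost no list could pass there, and a list that failed is not decided by it. Adjusted p-values for lists are over the 28 lists. For pairs of single arrays, the median of a list was set against 10000 random lists.

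The steps were tested on simulated data with known changes, built on the real array sets. The noise was independent between probe sets and arrays, and the set shift was the same in every group, as the block assumes. For E2-BSA against control the blocked fit recovered 0% of probe sets changed by 0.5, 4.48% of those changed by 1 and 93.9% of those changed by 2 on the log2 scale, and the fit without the block recovered 0% at each size. For E2-BSA over 3 backgrounds the blocked fit recovered 23.9%, 92.5% and 100%, and the fit without the block 0%, 38.8% and 89.4%. The other alternatives were quantile normalization, the replicate number as a block, the compared groups alone, vehicles pooled with control, each array left out in turn, the mean of a gene's probe sets for the lists, and 50 or 1000 probe sets in the carried-over response. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.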

Results

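Gene expression was measured in T47D, an established human breast cancer cell line that expresses estrogen and progesterone receptors, on 11 Affymetrix whole-genome arrays, 1 sample of total RNA per array. The cells were held for 4 h in medium with 10% charcoal-stripped serum, which is depleted of steroids, and then treated for 3 h. The 11 arrays formed 9 groups. Untreated control and E2-BSA, estradiol coupled to bovine serum albumin, had 2 arrays each, and the other 7 groups had 1 array each. These were estradiol, its vehicle ethanol at 0.1%, the carrier BSA, ICI, G15, E2-BSA with ICI and E2-BSA with G15. The stated concentrations were 1 µM for estradiol, E2-BSA and BSA and 10 µM for ICI and G15. The labels call ICI and G15 antagonists. G15 is known as an antagonist of GPER1, the G protein-coupled estrogen receptor, and ICI is named in the labels by this abbreviation alone. The series is described as a time course, but every label gave 3 h. The labels did not say that the 2 arrays of a group came from separate cultures. The p-values of single probe sets therefore measured only the spread between these arrays, which can be technical. Camera p-values at the preset correlation rested on the spread between genes, so a very low one is no evidence of replication between arrays. The small number of arrays limited the precision of every comparison.

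The 11 arrays separated into 2 sets that crossed the groups. Control 1, E2-BSA 1 and estradiol formed a smaller set of 3 arrays, and the other 8 arrays formed a larger set. The first principal component separated them and held 71.0% of the variance, against 5.65% for the second. Array-wide correlations of the centred values were 0.824 to 0.864 within the smaller set, 0.160 to 0.466 within the larger set and -0.584 to -0.330 between the sets. The control probe sets of the array moved with this split. The difference between the 5′ and 3′ probe sets of ACTB, a measure of RNA integrity and of the length of the labelled product, was 0.737 ± 0.0760 (SD, n = 3) in the smaller set and -0.111 ± 0.132 (SD, n = 8) in the larger, on the centred log2 scale. The same difference for GAPDH was 0.452 ± 0.0854 (SD, n = 3) against -0.121 ± 0.0807 (SD, n = 8). The probe sets for 18S ribosomal RNA averaged 1.54 ± 0.0918 (SD, n = 3) against -0.208 ± 0.160 (SD, n = 8). Control 1 and control 2 differed by a log2 value of 1 or more in 3742 probe sets, and E2-BSA 1 and E2-BSA 2 in 3172. Within a set, E2-BSA 1 differed from control 1 in 152 probe sets and E2-BSA 2 from control 2 in 55. Because both replicated groups had an array in each set, every comparison was fitted without and with the array set as a block. The block was chosen after the data were seen.

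**Figure D1:**
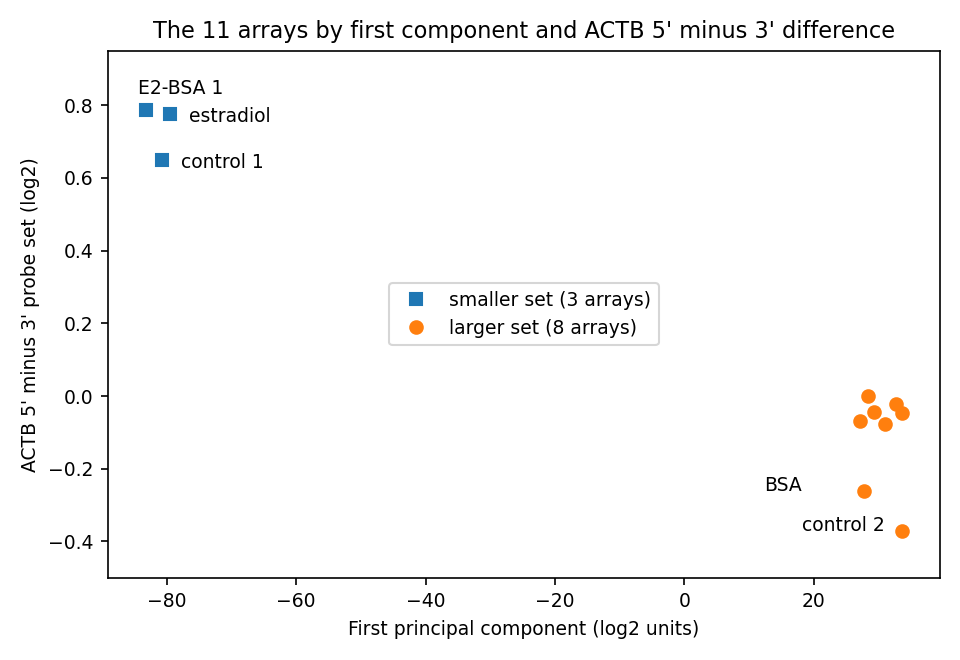
Each point is 1 of the 11 arrays, with its score on the first principal component (log2 units) on the horizontal axis and the difference between the 5′ and 3′ probe sets of ACTB (centred log2) on the vertical axis. The 3 arrays of the smaller set, control 1, E2-BSA 1 and estradiol, lie between 0.650 and 0.786 on the vertical axis, and the 8 arrays of the larger set between -0.371 and 0.000372.

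The comparison of E2-BSA with untreated control asked which transcripts respond within 3 h to the conjugated hormone, which is used as a form that does not cross the cell membrane. With the array set as a block, genes of the estrogen response rose. The potassium channel gene KCNK5 rose by 2.10 ± 0.13 on the log2 scale (SE; adjusted p = 3.58e-05), a 4.29-fold change, and the transcription factor gene MYC rose by 2.12 ± 0.17 (adjusted p = 0.00015), a 4.35-fold change. The chemokine gene CXCL12 rose by 2.16 ± 0.22 (adjusted p = 0.000868), and RASGRP1, which encodes an activator of Ras, rose by 2.15 ± 0.21 (adjusted p = 0.000599). Among the genes that fell were ID2, by 1.30 on the log2 scale, ID1, by 1.08, which both encode inhibitors of helix-loop-helix transcription factors, and the Wnt antagonist gene DKK1, which fell by 1.17.

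KCNK5, MYC and ID1 moved the same way in both array sets. KCNK5 was higher by 2.29 in E2-BSA 1 than in control 1 and by 1.91 in E2-BSA 2 than in control 2, and MYC by 2.55 and 1.69. The corresponding differences of ID1 were -1.21 and -0.96. Other genes with the highest changes were MAFF (1.92), ADRA2A (1.91), PLCL1 (1.81), MYB (1.67), STC2 (1.62), KCTD6 (1.61), MAP6D1 (1.60) and RET (1.49), with adjusted p from 0.00015 to 0.000888. Other genes that fell were FLRT3 (-1.32), SLITRK6 (-1.14), AMIGO2 (-1.14), FBXO32 (-1.01), IFIT3 (-0.98), PALMD (-0.96), RNF43 (-0.91), FTX (-0.91) and ANK3 (-0.89), with adjusted p from 0.000888 to 0.0113.

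In all, limma called 359 of 54613 probe sets with the block, 208 higher and 151 lower, and these covered 142 named genes that rose and 70 that fell. Without the block, the fit fixed before the data were examined called 0 probe sets, with 339 at an unadjusted p under 0.05 against 5287 with the block. With the block this comparison had 1 residual degree of freedom, and leaving out any of the 4 arrays left none, so no call could be tested without each array. The calls also rested on the scale of the deposited values. After quantile normalization the blocked limma fit called 0 probe sets, with 3942 at an unadjusted p under 0.05. All 359 kept their sign, and their median absolute change was 0.75 against 0.77. KCNK5 was then at 1.92 ± 0.30 (SE; adjusted p = 0.504) and MYC at 1.92 ± 0.26 (adjusted p = 0.504). In simulated data the blocked fit recovered 93.9% of probe sets changed by 2 on the log2 scale and 4.48% of those changed by 1, and the fit without the block recovered 0%. Those data had independent noise and the same set shift in every group, as the block assumes, so they do not test the 359 calls.

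**Figure D2:**
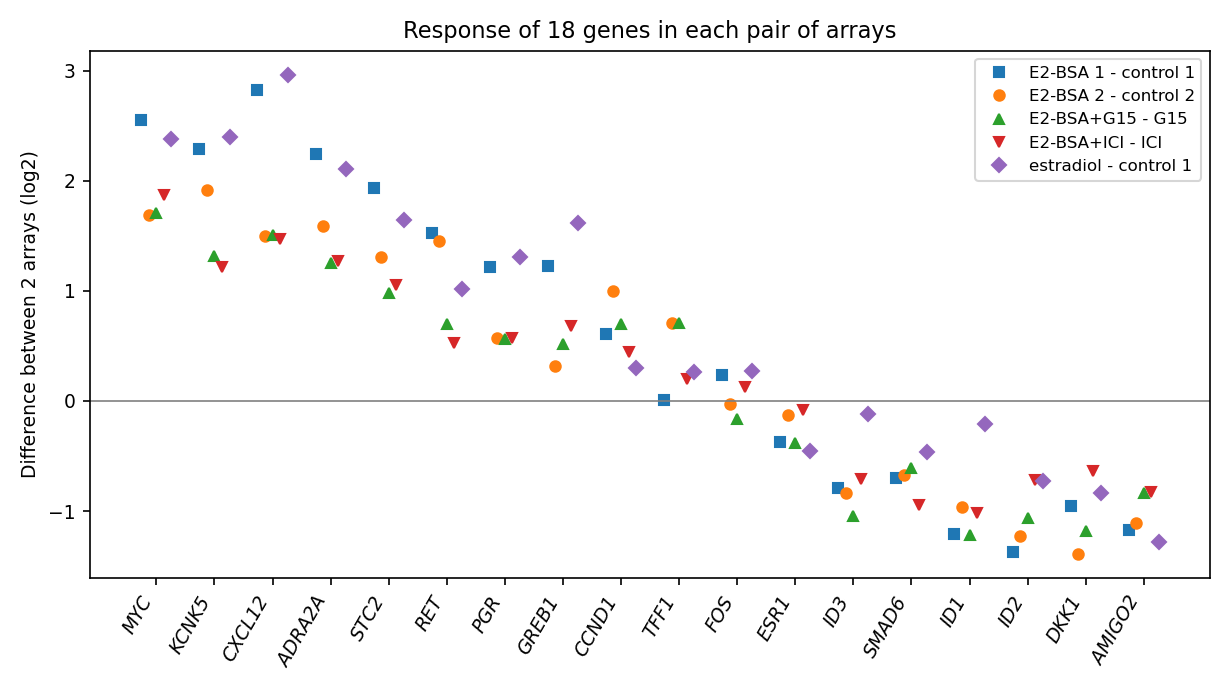
Log2 differences (vertical axis) of 18 genes (horizontal axis) between pairs of single arrays, 1 symbol per pair, with no replicate of a pair. MYC was higher in all 5 pairs, from 1.69 to 2.55, and ID1 lay between -1.22 and -0.96 in the 4 E2-BSA pairs and at -0.21 in estradiol minus control 1. MYC was itself at -1.87 in ICI minus control 2, so in the pair with ICI it rose from a lowered level.

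Gene groups fixed before the data were examined were described for the same blocked comparison. Of the 40 measured estrogen-induced targets, 23 rose and 1, AMIGO2, fell over all genes tested, and 33 rose and 1 fell when adjusted over the list alone. The median change was 0.73, and 39 of the 40 had a positive value, with TPBG (1.25), MYBL1 (1.29), SIAH2 (1.17) and RARA (1.07) among those that rose. The camera test placed the list above other genes (adjusted p = 1.77e-44), with adjusted p = 0.701 with an estimated correlation. Of 16 measured TGF-beta and Wnt feedback genes, 7 fell (ID1, ID2, ID3, DKK1, RNF43, SMAD6 and BAMBI), 0 rose and 9 did not pass. Adjusted over the list alone, 9 fell and 2 rose. The median was -0.41 and camera gave adjusted p = 4.93e-09, against adjusted p = 0.701 with an estimated correlation.

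Of 19 interferon-stimulated genes, IFIT3 (-0.98), IFIT2 (-0.82), IFIT1 (-0.73) and IRF9 (-0.65) fell, 0 rose, and 6 fell and 1 rose when adjusted over the list alone. The median was -0.19 (camera adjusted p = 2.18e-07, and adjusted p = 0.701 with an estimated correlation). Of 24 immediate early genes, MYC, EGR3 (0.93), IER3 (0.82) and KLF10 (0.74) rose and 0 fell, and 7 rose when adjusted over the list alone. FOS was at 0.10 (adjusted p = 0.882). That list had a median of 0.17 (camera adjusted p = 3.9e-06, and adjusted p = 0.701 with an estimated correlation). Of 15 estrogen-repressed targets, IL1R1 (-0.82) and SMAD6 (-0.69) fell, 4 fell and 1 rose when adjusted over the list alone, and the median was -0.15 (camera adjusted p = 0.00929, and adjusted p = 0.78 with an estimated correlation). The hypoxia genes PFKFB3 (1.10) and ADM (0.82) rose among 17 measured, 3 when adjusted over the list alone (camera adjusted p = 0.0102, and adjusted p = 0.889 with an estimated correlation). None of 25 mitosis genes passed the test over all genes or adjusted over the list alone, and their median was -0.13 (camera adjusted p = 3.71e-05, and adjusted p = 0.701 with an estimated correlation). None of 9 genes reported as GPER targets passed over all genes, 2 rose when adjusted over the list alone, and their median was 0.15 (camera adjusted p = 0.00929, and adjusted p = 0.78 with an estimated correlation). Of 28 lists, 11 passed camera and 0 of them held with an estimated correlation. With 1 residual degree of freedom that alternative could hardly pass any list, so it does not decide.

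The receptors themselves did not pass the test. The blocked E2-BSA effect was -0.25 ± 0.12 for ESR1 (SE; adjusted p = 0.556), -0.03 ± 0.16 for ESR2 (adjusted p = 0.986) and 0.05 ± 0.12 for GPER1 (adjusted p = 0.956). The progesterone receptor gene PGR rose by 0.90 ± 0.15 (adjusted p = 0.0177) and the cyclin D1 gene CCND1 by 0.80 ± 0.13 (adjusted p = 0.0158). GREB1, a target of estrogen receptor, was at 0.77 ± 0.18 (adjusted p = 0.0856). TFF1, another classical target, was at 0.36 ± 0.15 (adjusted p = 0.471), and it differed by array set. Its values were -2.46, -2.45 and -2.20 on control 1, E2-BSA 1 and estradiol, against 0.02 on control 2 and 0.72 on E2-BSA 2.

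E2-BSA was also averaged over 3 backgrounds (no antagonist, ICI and G15), 4 arrays with it against 4 without. With the array set as a block, MYC rose by 1.95 ± 0.14 (SE; adjusted p = 0.00754), CXCL12 by 1.82 ± 0.21 (adjusted p = 0.0268) and KCNK5 by 1.68 ± 0.17 (adjusted p = 0.0195). MAFF (1.66), ADRA2A (1.59), GATA4 (1.35), STC2 (1.32), RUNX2 (1.32), KCTD6 (1.30), MPPED2 (1.29), RBM24 (1.27) and CISH (1.25) rose as well. ID1 fell by 1.10 ± 0.08 (adjusted p = 0.00754), and ID2 (-1.09), DKK1 (-1.04), FLRT3 (-1.04), AMIGO2 (-0.98), SLITRK6 (-0.96), SHISA2 (-0.86), ID3 (-0.85), NR2F1 (-0.76), EPHA4 (-0.76), IL1R1 (-0.73) and SMAD6 (-0.73) fell. In total 133 probe sets passed, 103 higher and 30 lower, of which 115 had also passed in the blocked comparison of E2-BSA with control, which shares 4 of the 8 arrays. The fit without the block called 0 probe sets in limma, with 1203 at an unadjusted p under 0.05. The blocked count fell to 0 without control 2, E2-BSA 2, G15 or E2-BSA with G15, to 2 without control 1 or E2-BSA 1, and to 95 without ICI or E2-BSA with ICI. Leaving out either array of a pair with the same background and array set is the same fit, since the other array is then fitted exactly. After quantile normalization the blocked count was 1, CXCL12 at 1.85 ± 0.09 (adjusted p = 0.0102), while MYC was at 1.60 ± 0.31 (adjusted p = 0.282) and all 133 kept their sign.

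The gene lists in this comparison were tested as fixed, without the block. Estrogen-induced targets had a median of 0.56 with 39 of 40 positive. None passed over all genes, and 18 rose and 1 fell when adjusted over the list alone (camera adjusted p = 1.67e-33, and adjusted p = 0.0463 with an estimated correlation). TGF-beta and Wnt feedback genes had a median of -0.37, with 7 of 16 lower when adjusted over the list alone (camera adjusted p = 7.67e-10, and adjusted p = 0.0463 with an estimated correlation). Of 28 lists, 6 passed camera, and these were the 2 that held with an estimated correlation. The other 4 were estrogen-repressed targets with a median of -0.20 (adjusted p = 0.35 with an estimated correlation), immediate early genes with 0.09 (adjusted p = 0.35 with an estimated correlation), interferon-stimulated genes with -0.24 (adjusted p = 0.389 with an estimated correlation) and hypoxia targets with 0.04 (adjusted p = 0.481 with an estimated correlation). With the block, 10 estrogen-induced targets rose and AMIGO2 fell over all genes (33 and 1 adjusted over the list alone), and 6 of 16 feedback genes fell (8 lower and 2 higher adjusted over the list alone). The 2 camera calls then had adjusted p = 0.385 and adjusted p = 0.18 with an estimated correlation.

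E2-BSA was compared with its carrier BSA. With the block, KCNK5 rose by 2.08 ± 0.17 (SE; adjusted p = 0.000886), ADRA2A by 2.08 ± 0.20 (adjusted p = 0.00248), MYC by 1.99 ± 0.23 (adjusted p = 0.00456), RASGRP1 by 1.94 ± 0.28 (adjusted p = 0.018) and CXCL12 by 1.83 ± 0.30 (adjusted p = 0.0347). FLRT3 (-1.79), ID2 (-1.51), DKK1 (-1.42), IFIT3 (-1.39) and SHISA2 (-1.28) fell. Of 40 estrogen-induced targets, 10 rose and AMIGO2 fell (27 and 1 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.24e-34, and adjusted p = 0.827 with an estimated correlation). The blocked fit called 66 probe sets higher and 17 lower, and 0 after quantile normalization, with 7494 at an unadjusted p under 0.05. In limma without the block 0 passed, with 306 at an unadjusted p under 0.05. Within the larger set, E2-BSA 2 differed from BSA by 1 or more in 76 probe sets.

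BSA alone was compared with untreated control. With the block, NASP, which encodes a histone chaperone, fell by 1.76 ± 0.17 (SE; adjusted p = 0.0124), the nuclear pore gene TPR by 1.64 ± 0.17 (adjusted p = 0.0147), the RNA helicase gene DHX9 by 1.58 ± 0.18 (adjusted p = 0.0163), the nuclear noncoding RNA MALAT1 by 1.41 ± 0.16 (adjusted p = 0.0163) and the spindle gene ASPM by 1.40 ± 0.20 (adjusted p = 0.033). The same genes had low values on other single arrays that share control 2 as a baseline. NASP was at -1.01 in ICI minus control 2 and -1.05 in G15 minus control 2, and MALAT1 at -0.99 and -1.16. No gene rose, and the positive values with the lowest p were BTG4 (0.83, adjusted p = 0.125) and SGPP1 (0.81, adjusted p = 0.146). The blocked fit called 27 probe sets, all lower. It had 2702 at an unadjusted p under 0.05, which lies below the share of 0.05 expected with no change. After quantile normalization it called 0, with 6273 at an unadjusted p under 0.05. Without the block limma called 0, with 245 at an unadjusted p under 0.05, and 0 of 28 lists passed camera in either fit.

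Free estradiol was compared with untreated control in the same way. With the block, CXCL12 rose by 2.63 ± 0.30 (SE; adjusted p = 0.00546), KCNK5 by 2.30 ± 0.17 (adjusted p = 0.000498), MYC by 2.16 ± 0.23 (adjusted p = 0.00405), MYB by 2.06 ± 0.23 (adjusted p = 0.00546), PGR by 1.15 ± 0.20 (adjusted p = 0.0476) and GREB1 by 1.39 ± 0.23 (adjusted p = 0.0387). SHISA2 (-1.33), AMIGO2 (-1.26), FLRT3 (-1.24), SLITRK6 (-1.10), ST8SIA1 (-1.09), GNAI1 (-1.04) and NR2F1 (-1.03) fell. Of 40 estrogen-induced targets, 15 rose and AMIGO2 fell (29 and 1 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 8.2e-36, and adjusted p = 0.795 with an estimated correlation). The blocked fit called 82 probe sets higher and 9 lower, and 0 after quantile normalization, with 822 at an unadjusted p under 0.05. Without the block limma called 0, with 412 at an unadjusted p under 0.05. This comparison was added after the data were seen, because the estradiol array lies in the smaller set with control 1. The planned contrast of estradiol with the mean of the control and ethanol arrays called 69 higher and 15 lower with the block, and 0 without it, with 603 at an unadjusted p under 0.05. After quantile normalization its blocked fit called 0, with 1255 at an unadjusted p under 0.05. It gave 2.59 for CXCL12 and 2.35 for KCNK5, and it also placed TNFAIP3 (-1.38) and CCL20 (-1.31) lower, which were high on the ethanol array.

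Estradiol against its own vehicle was a comparison of 2 single arrays from different array sets, with no replicate check. It gave 3160 probe sets with a difference of 1 or more, 1793 higher and 1367 lower, beside 3742 between the 2 control arrays. After quantile normalization the count was 1180, and against control 1, in the same set, it was 113. The highest differences were in ANP32E (4.36), SGPP1 (3.43), SYT1 (3.25), FAR1 (3.19), ITGB1 (3.16) and CDK1 (3.13). The lowest were in CHAC1 (-3.71), MAFF (-3.20), IRF1 (-3.16), INHBE (-3.01), ICAM1 (-3.01) and ATF3 (-2.98). Estrogen-induced targets had a median of 0.38, above all of 10000 random lists of that size (percentile 100). NF-kB targets (-1.19) and genes of the unfolded protein and integrated stress response (-1.04) lay below them all (percentile 0), and mitosis genes (0.80) above (percentile 100). In estradiol minus control 1 the medians were 0.75 for estrogen-induced targets (percentile 100), 0.03 for NF-kB targets (percentile 61.5), 0.18 for the stress response (percentile 99.3) and -0.01 for mitosis (percentile 34.9). The difference of these 2 arrays holds both array set and treatment, which the blocked contrasts separate on the assumption that the set difference is the same in every group.

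Free and conjugated estradiol, both stated at 1 µM and 3 h, were compared directly with the array set as a block. The labels did not say whether the E2-BSA concentration refers to the conjugate or to the estradiol it carries. MYC differed by 0.04 (95% confidence interval -0.45 to 0.53), KCNK5 by 0.20 (-0.17 to 0.58), ADRA2A by 0.03 (-0.40 to 0.47) and CXCL12 by 0.47 (-0.17 to 1.11). Larger values, none of which passed, were those of IFIT1, at 1.25 (0.89 to 1.61; adjusted p = 0.166), IFIT3, at 0.96 (0.60 to 1.31; adjusted p = 0.32), and ID1, at 0.94 (0.58 to 1.29; adjusted p = 0.32). Interferon-stimulated genes had a median difference of 0.46, with 0 of 19 passing over all genes and 11 higher when adjusted over the list alone (camera adjusted p = 2.04e-09, and adjusted p = 0.762 with an estimated correlation). TGF-beta and Wnt feedback genes had a median of 0.28, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00145, and adjusted p = 0.762 with an estimated correlation). In all, 8 of 28 lists passed camera in this blocked comparison, 4 higher and 4 lower. No probe set passed in limma with or without the block, with 4644 and 293 at an unadjusted p under 0.05. The planned contrast, which first subtracts ethanol from estradiol and BSA from E2-BSA, called 4 higher and 34 lower with the block and 0 without it, with 217 at an unadjusted p under 0.05. With the block and quantile normalization it called 0, with 4125 at an unadjusted p under 0.05. Its lowest values, MAFF (-5.40), CHAC1 (-3.97), CCL20 (-3.49), INHBE (-3.47) and TNFAIP3 (-3.36), were genes high on the ethanol array, and its highest, PIF1 (1.93) and TOP2A (1.75), were low there.

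On the ethanol array, stress and inflammatory genes were high against untreated control. With the block, MAFF rose by 4.73 ± 0.20 (SE; adjusted p = 5.5e-07), a 26.6-fold change, the integrated stress response gene CHAC1 by 3.74 ± 0.18 (adjusted p = 8.81e-07), ATF3 by 3.41 ± 0.16 (adjusted p = 8.81e-07), TNFAIP3, which encodes an inhibitor of NF-kB signalling, by 3.39 ± 0.19 (adjusted p = 2.42e-06), and the stress cytokine gene GDF15 by 3.30 ± 0.21 (adjusted p = 9.09e-06). PIF1 (-1.60), TOP2A (-1.38), ASPM (-1.34), PSRC1 (-1.26) and KIF14 (-1.23), genes of DNA metabolism and mitosis, fell. Of these, ASPM was also at -1.24 in BSA minus control 2, which shares control 2 as a baseline. Of 17 NF-kB targets 10 rose and 0 fell, with CXCL2 (3.21), CCL20 (2.97) and ICAM1 (2.11) among them (13 adjusted over the list alone, median 1.01). Of 21 genes of the unfolded protein and integrated stress response 11 rose, with DDIT3 at 2.45 and SLC7A11 at 2.16 (14 adjusted over the list alone, median 0.99). Of 24 immediate early genes 7 rose, with DUSP1 at 2.33 and JUN at 2.27 (18 adjusted over the list alone, median 0.56). Of 25 mitosis genes 7 fell, with PLK1 at -1.19 (23 adjusted over the list alone, median -0.64). Among 16 p53 targets GDF15, CDKN1A (1.05), MDM2 (1.05) and TNFRSF10B (0.89) rose (5 adjusted over the list alone). Camera adjusted p was from 7.29e-33 to 1.1e-09 for these 5 lists, and each had adjusted p = 0.427 with an estimated correlation. In all, 16 of 28 lists passed camera in this blocked comparison, 15 higher and 1 lower, so a camera call was not particular to these 5.

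The blocked fit called 124 probe sets higher and 33 lower on the ethanol array. No probe set passed in limma without the block, with 417 at an unadjusted p under 0.05. After quantile normalization the blocked fit called 12, among them ATF3 (2.43), CXCL2 (2.13), CCL20 (1.92) and PIF1 (-2.01), and MAFF was at 3.46 ± 0.62 (SE; adjusted p = 0.154). In ethanol minus control 2, inside the larger set, 110 probe sets differed by 1 or more. The group is a single array, assumed to vary like the 2 replicated groups.

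**Figure D3:**
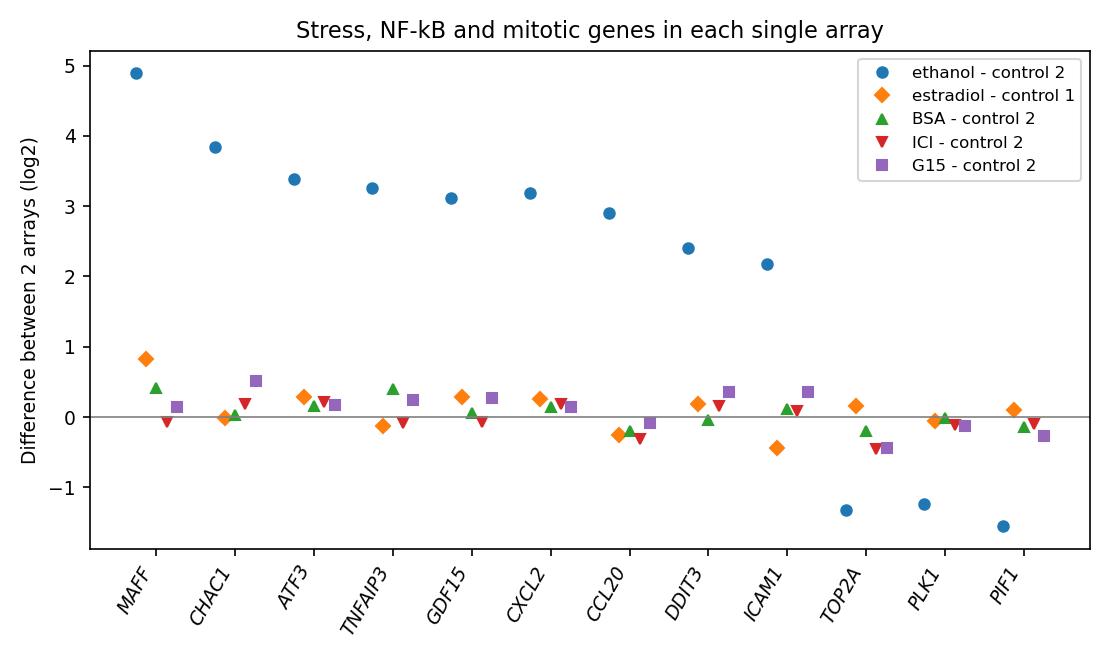
Log2 differences (vertical axis) of 12 genes (horizontal axis) between each single treated array and the control array of its own set, 1 symbol per treatment. MAFF was at 4.89 in ethanol minus control 2 and at 0.83 in estradiol minus control 1, and TOP2A at -1.31 and 0.16.

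ICI and G15 alone gave no call against untreated control. With ICI, MYC had the lowest value, at -1.66 ± 0.23 with the block (SE; adjusted p = 0.196), and it was -2.80 on the ICI array against -0.93 on control 2. Other low values were LUC7L3 (-1.20), TPR (-1.17), ANKFN1 (-1.08), ZFR (-1.04) and LARS1 (-1.02), and high values were CIMAP1B (0.96) and CCL7 (0.85), with adjusted p from 0.196 to 0.432. With G15, FBXO32, which encodes a ubiquitin ligase component, was at -1.39 ± 0.16 (adjusted p = 0.0577) and DUSP6, which encodes a phosphatase of ERK, at -1.93 ± 0.26 (adjusted p = 0.107), while the interferon-stimulated genes IFI27 and ISG15 were at 1.22 ± 0.16 (adjusted p = 0.107) and 0.97 ± 0.16 (adjusted p = 0.239). Of 19 interferon-stimulated genes 0 passed over all genes and 8 rose when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 4.14e-08, and adjusted p = 0.97 with an estimated correlation). With ICI that list had a median of -0.11, with 2 lower adjusted over the list alone (camera adjusted p = 0.0438, and adjusted p = 0.954 with an estimated correlation). With the block limma called 0 probe sets for ICI, with 3250 at an unadjusted p under 0.05, and 0 for G15, with 2643. Without it the counts were 0 with 294 and 0 with 135. Of these counts at an unadjusted p under 0.05, all but 3250 lie below the share of 0.05 expected with no change.

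The antagonists were then set against the E2-BSA response. In E2-BSA with ICI against ICI alone, MYC was higher by 1.87, CXCL12 by 1.47, ADRA2A by 1.27 and KCNK5 by 1.22, and ID1 was at -1.01. In E2-BSA with G15 against G15 alone the same genes were at 1.71, 1.51, 1.25, 1.32 and -1.22. MYC was at -1.87 in ICI minus control 2, so its rise of 1.87 with ICI present brought it back to the control level. Estrogen-induced targets had blocked medians of 0.30 with ICI (9 rose and 1 fell adjusted over the list alone) and 0.55 with G15 (23 and 1). Without antagonist the median was 0.73 over both array sets, and 0.56 in E2-BSA 2 minus control 2, the pair of the larger set to which the antagonist arrays belong. The differences themselves were tested as interactions. With ICI the estrogen-induced targets had a median interaction of -0.35, negative in direction with 4 of 40 positive, 0 passing over all genes and 2 lower adjusted over the list alone (camera adjusted p = 2.4e-08, and adjusted p = 0.918 with an estimated correlation). Inside the larger set the median difference between the responses with and without ICI was -0.19 (middle 95% of random lists -0.11 to 0.07), and that for G15 was 0.01 (-0.11 to 0.08). With ICI, RET had a low value that did not pass (-0.96, adjusted p = 0.122). With G15 that list had a median of -0.12 and did not pass camera (adjusted p = 0.165). Mitosis genes did, with a median of 0.23, 0 of 25 passing over all genes and 4 higher adjusted over the list alone (camera adjusted p = 0.000119, and adjusted p = 0.935 with an estimated correlation). The interaction of MYC was -0.25 with ICI (95% confidence interval -0.89 to 0.39) and -0.42 with G15 (-1.06 to 0.22).

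For single probe sets, the blocked ICI interaction called 6, all higher, of which CFLAR and FBXO32 had a gene name, and 0 when only probe sets with 1 gene were tested. After quantile normalization the count was also 0, with 5973 at an unadjusted p under 0.05. Without the block limma called 0, with 207 at an unadjusted p under 0.05. The G15 interaction called 0 in both fits, with 4377 at an unadjusted p under 0.05 with the block and 184 without. The blocked fit called 0 probe sets for E2-BSA with ICI against ICI, with 3901 at an unadjusted p under 0.05, and 53 higher and 8 lower for E2-BSA with G15 against G15, which became 0 after quantile normalization, with 7685 at an unadjusted p under 0.05. Without the block limma called 0 for both, with 211 and 224 at an unadjusted p under 0.05.

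The response was followed across arrays that share no control. Among the 200 probe sets with the lowest p in E2-BSA against control without the block, 74% moved the same way in E2-BSA with ICI minus ICI (95% Clopper-Pearson interval 67.3% to 79.9%), 76.5% in E2-BSA with G15 minus G15 (70.0% to 82.2%) and 80.5% in estradiol minus ethanol (74.3% to 85.8%). Estradiol minus ethanol crosses the array sets and includes the genes high on the ethanol array, so its share is not a measure of the response alone. Probe sets are not independent, so these intervals cover counting error alone. Ranked by E2-BSA 2 minus control 2 instead, 96% of the top 200 moved the same way in E2-BSA 1 minus control 1 and 84.5% in estradiol minus control 1. The 78 probe sets that differed by 1 or more in the same direction in both E2-BSA 1 and estradiol against control 1, 73 of them higher, were then read in the larger set. Signed by that direction, their median was 0.83 in E2-BSA 2 minus control 2, 0.59 in E2-BSA with ICI minus ICI and 0.85 in E2-BSA with G15 minus G15. It was 0.01 in BSA minus control 2, 0.03 in G15 minus control 2 and -0.19 in ICI minus control 2. In E2-BSA with ICI it was 0.34 against control 2 and -0.47 against E2-BSA 2.

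**Figure D4:**
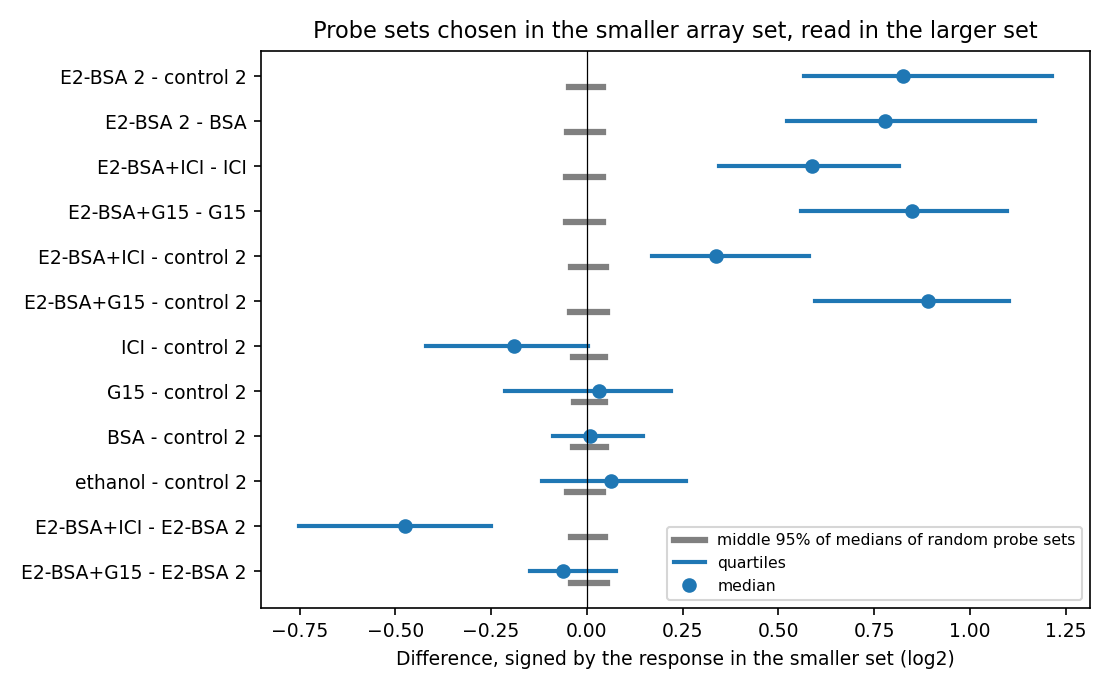
Differences between pairs of arrays of the larger set (vertical axis) for the 78 probe sets chosen in the smaller set, signed by their direction there (horizontal axis, log2). Points are medians, thin lines run from the lower to the upper quartile, and grey bars show the middle 95% of medians of random probe sets. The median of E2-BSA 2 minus control 2 is 0.83 and that of E2-BSA with ICI minus E2-BSA 2 is -0.47.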

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

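The tests of the array split, of the ethanol array and of the ICI background were chosen after the results were seen, and the counts over other splits of the arrays were planned before those counts were seen, those with the block after the array sets had been found.

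CFLAR, which encodes an inhibitor of caspase 8 signalling, and FBXO32 stood out in the test of whether the E2-BSA response differs between cells with and without ICI. With the array set as a block, the interaction was 1.63 for CFLAR (SE 0.21, limma adjusted p = 0.0454) and 1.58 for FBXO32 (SE 0.21, adjusted p = 0.0454). CFLAR was at -0.61 on the ICI array and 0.68 on the array with E2-BSA and ICI, against -0.02 and 0.09 on the control and -0.24 and -0.37 on the E2-BSA arrays. FBXO32 was at 0.54 and 0.68 on control, -0.50 and -0.30 on E2-BSA, -0.17 on ICI and 0.40 on the combination. For FBXO32 the interaction with G15 was 1.44 (SE 0.21, adjusted p = 0.0867), which did not pass. Both interactions subtract the same E2-BSA effect, -1.01 for FBXO32, so their likeness does not decide whether the difference is particular to ICI. Each value with an antagonist is a single array, and 0 probe sets passed for ICI when those with 1 gene alone were tested or after quantile normalization.

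The first pattern is the separation of 3 arrays from the other 8. Treatment is excluded as its cause, because 2 groups, control and E2-BSA, have arrays on both sides. RNA integrity or labelling remains open: the 5′ minus 3′ differences of ACTB and GAPDH separate the sets without overlap, with gaps of 0.649 and 0.394. A different estrogen state of the cultures may also contribute. The estrogen-induced targets had a median of -0.31 in control 1 minus control 2, below the middle 95% of random lists (-0.12 to 0.17), with 13 of 40 at -1 or lower.

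The split bears on the count of calls for E2-BSA over 3 backgrounds. Without the block the real count was 0, which all 34 of 34 splits of the 8 arrays reach by definition, so these splits say nothing about chance. The highest other, a split that follows the array sets, gave 17019 calls, which points to a structure of the samples. With the block the real count was 133, the highest of the other splits gave 0, and 1 of 32 splits was as large. That share does not decide, because most of these splits exchange arrays between array sets or backgrounds, which the model treats as different. Only 8 splits exchange arrays within a pair of the same set and background, too few for a share under 0.05, and the highest of the others there gave 0. For gene lists, 6 passed, 3 of 34 splits gave as many and the highest other gave 8. With the block 6 passed, 4 of 32 splits gave as many and the highest other gave 9, so chance is excluded for neither count of lists.

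The second pattern is the stress, NF-kB and immediate early program on the ethanol array. Ethanol as its cause was read on the estradiol array, which by the labels' implication received ethanol as vehicle, in an amount not given. The 124 probe sets higher on the ethanol array had a median of 0.0591 in estradiol minus control 1, against 1.09 in ethanol minus control 2. This argues against ethanol as the whole cause. That array also held estradiol, so an effect of ethanol that estradiol counters is not excluded. The list of the unfolded protein and integrated stress response had a median of 0.18 in estradiol minus control 1 (percentile 99.3 among random lists). RNA integrity or labelling, as far as the 5′ minus 3′ differences of ACTB and GAPDH measure it, is excluded as the cause of the whole program. The ACTB difference of the ethanol array, 0.000372, is the highest of its set, but it is 0.650 on control 1, where the same probe sets had a median of 0.115 against control 2, with 10 of 124 at 1 or more against 84 on the ethanol array. The ICI array, with -0.0218 for ACTB, had a median of 0.03 and 0 at 1 or more. An event particular to that culture or array remains open and was not tested.

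The third pattern is the E2-BSA response in the presence of ICI. Arrays shared between selection and test are excluded, because the 78 probe sets chosen in the smaller set had a median of 0.59 in E2-BSA with ICI minus ICI (middle 95% of random probe sets -0.05 to 0.04). A return from a level lowered by ICI is excluded as the whole cause, with a median of 0.34 in E2-BSA with ICI minus control 2, although MYC itself returned to its control level (-0.93 on both arrays). A partial block by ICI may account for the smaller size, with a median of -0.31 for the response with ICI minus that without it inside the larger set (middle 95% of random probe sets -0.06 to 0.05), lower in 61 of 78. The same difference for G15 was -0.07 (-0.06 to 0.06), and each response with an antagonist rests on 2 single arrays. Free estradiol released from the conjugate, incomplete receptor blockade at 3 h and a receptor that ICI does not block were not tested and remain open.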

How the results depend on the processing

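The array set block and its leave-one-out counts, robust eBayes, quantile normalization and the compared groups alone with that block, the larger array set alone, the fit to probe sets with 1 gene, the additive fit of 11 arrays, the ranking with the block and the comparison with control 1 were chosen after the data were seen.

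The replicate number from the labels as a block, chosen before the data were examined, gave 359 calls for E2-BSA against control, 13946 against BSA, 13220 for BSA, 14381 for ethanol, 960 for estradiol against control and ethanol, 14781 for ICI, 13551 for G15, 6 for the ICI interaction, 0 for the G15 interaction, 38 for estradiol against E2-BSA and 133 for E2-BSA over 3 backgrounds, each against 0 without a block. Deviations of same-numbered control and E2-BSA arrays correlated at 0.857, but 2 groups of 2 do not show a pairing. The counts above 10000 follow from the construction, since the single arrays all carry the number 1 and this block places those of the larger set with the smaller set. The counts of 359, 6, 0, 38 and 133 equal those with the array set as a block, also by construction. For these comparisons both blocks act only between the arrays of control and E2-BSA, so they are the same fit. The replicate number is therefore no separate check of the array set block there. The array set as a block gave 359, 83 against BSA, 27 for BSA, 157 for ethanol, 84 for estradiol against control and ethanol, 6 for the ICI interaction, 38 for estradiol against E2-BSA and 133 over 3 backgrounds. It removes the split between the sets from the residual spread. ICI, G15 and the G15 interaction stayed at 0.

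Vehicles pooled with control gave 2 calls for E2-BSA against control, and 151 with the array set block. The additive fit of 11 arrays gave 133 in place of 359, since it is the fit over 3 backgrounds. That blocked count of 133 was 2 in the larger array set alone, as was the count of 0 without the block. It ranged from 0 to 95 when 1 array was left out (0 without control 2, E2-BSA 2, G15 or E2-BSA with G15, 2 without control 1 or E2-BSA 1), with fewer residual degrees of freedom each time. The 6 calls of the ICI interaction became 0 with probe sets of 1 gene. Estradiol against ethanol gave 242 at a log2 difference of 2, 1180 after quantile normalization and 113 against control 1, in place of 3160. The 6 gene lists became 2 with an estimated correlation and 1 with fry, and 5 to 7 when 1 array was left out. The carried-over share was 98% with 50 and 62.2% with 1000 probe sets for ICI in place of 74%, 96% and 61.8% for G15 in place of 76.5%, and 96% and 67.6% for estradiol in place of 80.5%. Ranking with the array set block gave 87.5% for G15. The cause of these shifts was not tested.

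Quantile normalization ended nearly all calls of the blocked fits, with 0 in place of 359 for E2-BSA against control, 0 in place of 83 against BSA, 0 in place of 27 for BSA, 12 in place of 157 for ethanol, 0 in place of 84 for estradiol against control and ethanol, 0 in place of 6 for the ICI interaction, 0 in place of 38 for estradiol against E2-BSA and 1 in place of 133 over 3 backgrounds. It brings the SD of every array to 0.238, which was 0.405 to 0.420 in the smaller set and 0.161 to 0.194 in the larger, and the prior degrees of freedom went from 11.3 to 5.50. For E2-BSA against control MYC was at 1.92 ± 0.26 (SE) against 2.12 ± 0.17, and all 359 kept their sign. Ethanol gave lower sizes for its highest genes, with MAFF at 3.46 against 4.73 and CHAC1 at 2.36 against 3.74, and the median size of the 91 calls of estradiol against control went from 1.19 to 0.84. The median size of the calls rose in other comparisons, from 1.10 to 1.24 for ethanol, 1.18 to 1.41 for E2-BSA against BSA, 1.23 to 1.33 for BSA, 1.65 to 2.09 for the ICI interaction, 1.21 to 1.52 for E2-BSA with G15 against G15 and 0.76 to 0.87 over 3 backgrounds. With each set's mean removed, the SD was 0.129 to 0.147 in the smaller set and 0.120 to 0.160 in the larger. The gap in SD thus came mostly with the shift between the sets. Quantile normalization of the centred values therefore also rescaled differences inside a set, so the lost calls alone do not decide whether the calls hold. Which scale is right for these centred values was not tested. Robust eBayes moved no blocked count by over 1.5 times. The compared groups alone are the same fit for E2-BSA against control and the 2 interactions. Without the block the counts were 0 under quantile normalization, the compared groups alone and with a replicate left out, which says nothing about stability. Of 21 genes followed through these settings for E2-BSA against control, 16 passed with a block and not without. The 2 blocks are the same fit here. With a replicate left out and no block, called genes moved by over 1.5 times, with lowest sizes of -0.24 for DKK1 in place of -1.17, -0.22 for FLRT3 in place of -1.32 and 0.16 for CCND1 in place of 0.80 without E2-BSA 2, 0.74 for MYB in place of 1.67 and 1.33 for CXCL12 in place of 2.16 without control 1, and 0.50 for PGR in place of 0.90 without E2-BSA 1. Each of these differences then sets arrays of both sets against 1 array. GPER1, TFF1 and FOS, which did not pass, changed sign when an array was left out (TFF1 from 0.36 to -0.88 without control 1 and -1.23 without E2-BSA 2). The filters on mean expression, the eBayes trend and the pseudocounts were not run, because the deposited values are centred and keep no level.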

Other observations

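The test on feedback genes below was chosen after the result was seen.

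The 7 genes that fell among 16 TGF-beta and Wnt feedback genes were lower in each of the 4 E2-BSA pairs of arrays, while the other 9 did not pass. The 7 were called on the pairs E2-BSA 1 minus control 1 and E2-BSA 2 minus control 2, so only the pairs with ICI and G15 are a check. ID1 was at -1.21 in E2-BSA 1 minus control 1, -0.96 in E2-BSA 2 minus control 2, -1.01 in the presence of ICI and -1.22 in the presence of G15. ID3 was at -0.79, -0.84, -0.71 and -1.04, and SMAD6, an inhibitory SMAD, at -0.70, -0.68, -0.94 and -0.61. ID2 was at -1.37, -1.23, -0.71 and -1.06. In estradiol minus control 1, ID1 was at -0.21, ID3 at -0.12, RNF43 at -0.36 and SMAD6 at -0.47, while ID2 was at -0.73, BAMBI at -0.77 and DKK1 at -0.83. A hypothesis is that free estradiol lowers ID1 and ID3 less than E2-BSA does at 3 h. The median of the 16 genes in estradiol minus E2-BSA 1 was 0.21, but this does not decide, because the list was noticed for its low values with E2-BSA and E2-BSA 1 is among those arrays.

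The 19 interferon-stimulated genes had a negative median in the E2-BSA pairs without antagonist and with G15. It was -0.33 in E2-BSA 1 minus control 1 and -0.26 in E2-BSA 2 minus control 2, both below the middle 95% of random lists (-0.11 to 0.15 and -0.10 to 0.10). The median was 0.25 in G15 minus control 2 and -0.49 in E2-BSA with G15 minus G15, and IFI27 was at 1.28 and -1.44 in those pairs. In E2-BSA with G15 minus control 2 the list's median was -0.16 (middle 95% of random lists -0.11 to 0.11). Part of the -0.49 thus comes with a higher G15 array. For ICI the median was 0.13 in E2-BSA with ICI minus ICI, but -0.15 in ICI minus control 2 (middle 95% of random lists -0.09 to 0.11) and -0.02 in E2-BSA with ICI minus control 2 (-0.10 to 0.10), so the positive value comes with a lower ICI array. The median was 0.14 in estradiol minus control 1. The ICI interaction of the list had a blocked median of 0.51, with 0 of 19 passing over all genes and 6 higher when adjusted over the list alone (camera adjusted p = 2.4e-08, and adjusted p = 0.918 with an estimated correlation). Each pair with an antagonist as its baseline shares that array, with opposite sign, with the antagonist minus control 2.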
